A study of Mus musculus with 8 samples.

How the data were processed

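Gene expression was measured in 8 samples of mouse embryonic fibroblasts, each on its own one-colour array. Per the labels, biotin-labelled cRNA was made from 5 ug of total RNA by the standard Affymetrix protocol. The deposited table holds 1 log2 expression value per probe set and array, to 2 decimals. Per the submitters' processing notes these values come from RMA, with no version given. RMA subtracts background, forces the arrays to a common distribution and summarizes the probes of each probe set, so a change shared by all transcripts would not be visible in these values. Whether all 8 arrays were normalized together is not given in the sources used here, nor is a genome build. The log2 scale was taken from the values, which lay between 2.09 and 14.71 over the 45037 probe sets other than the 64 controls, and no further normalization was applied. The median log2 value per array lay between 5.01 and 5.12. For arrays, the number of arrays limits the precision, and 2 arrays per group leave 3 residual degrees of freedom in the fit described next, to which the moderation of variances added 5.22.

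Probe sets were named from the platform annotation. Of the probe sets other than controls, 34945 had exactly 1 gene symbol, 932 had several and were not used, and 9160 were not listed there and stay unnamed. Symbols were updated through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, in which 34741 probe sets found their identifier. That table also gave the order of genes along chromosomes, and no coordinates were used. A gene was represented by its probe set of highest mean over the 8 arrays, out of 18193 genes, 9010 of which had more than 1 probe set. Genes with a mean below the 25th percentile were left out, so 13647 genes were tested.

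The labels give 4 groups of 2 arrays: wild type in normoxia, knockout in normoxia, wild type in hypoxia and knockout in hypoxia. They mark 1 array of each group as belonging to a second set, and these 4 arrays are called replicate 2 or the second set here. The difference of the second from the first set was compared between groups across genes, and its correlation lay between 0.710 and 0.850 for the 6 pairs of groups, so arrays of a set deviate together. The correlation was highest between normoxia and hypoxia of one genotype, at 0.850 in wild type and 0.830 in knockout, so contrasts over both oxygen conditions rest in effect on 2 preparations per genotype. Nothing in the labels says that the arrays of a group came from separate cultures or embryos, so p-values measure the spread between these arrays, which may be technical.

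All tests used R 4.3.3 and limma 3.58.1. One linear model with a mean per group and the set as a further term was fitted to the log2 values of all 8 arrays, followed by eBayes with a mean-variance trend. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested are called changed. Counts of genes with an unadjusted p under 0.05 are to be read against a share of 0.05 of the tested genes. A well-calibrated test gives about that share where nothing changes. The contrasts were knockout against wild type in normoxia, in hypoxia and over both, hypoxia against normoxia in wild type, in knockout and over both, and the genotype by oxygen interaction, which is the hypoxia response of the knockout minus that of the wild type. Every adjusted p in the text for a gene comes from this limma fit. Errors given with log2 changes are standard errors of the fit.

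Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists of a contrast. The second form also rests on the 3 residual degrees of freedom, so a call lost there need not reflect a high correlation. For the ATF4 and unfolded protein response list the estimate was 0.00136, below the preset value. Its call for knockout against wild type in normoxia was lost all the same. Of 26 lists, 23 had at least 5 tested genes. Replication-dependent histones (2 tested genes), erythroid markers (3) and sex-linked genes (4) were too few for a list test. HIF target genes and glycolysis share 10 tested genes, and no other pair of lists shares more than 1. Counts called adjusted over the list alone use a Benjamini-Hochberg adjustment over the members of that list. All p-values are two-sided.

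The rule for the genes named in the text was fixed together with the lists, the comparisons, the tests and the alternatives before the data were examined, apart from the alternatives and tests that the closing section names as chosen later. It takes Egln2, Egln1, Egln3, Hif1a, Epas1 and Arnt, then in each of the 4 simple contrasts the 10 largest rises and 10 largest falls among called genes that moved the same way in both sets, and 5 and 5 in the other contrasts. It adds up to 4 members of each list with the smallest adjusted p. Genes of unknown function may be left out, which applied to 1 rise in wild type and 1 fall in knockout. Outside this rule are the members of lists too small for a test, the most abundant macrophage markers and the muscle markers of the closing section, Xist, Mt1 and H2-Ab1.

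The limma step was tested on simulated data with 13647 genes, real means and variances and known fold changes. For knockout against wild type in normoxia it recovered 55.2% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 98.5% of those changed 3-fold, and 7.69% of its calls were false. In hypoxia against normoxia in wild type the shares were 50.7%, 97.0% and 98.5%, with 6.29% false calls. For the interaction they were 10.4%, 68.7% and 95.5%, with 9.38% false calls. For knockout against wild type over both oxygen conditions they were 94.0%, 97.0% and 100%, with 5.37% false calls. The simulated errors were independent between arrays and genes, whereas the real normoxic and hypoxic arrays of one genotype and set deviate together. These shares therefore hold for independent errors only and may be too favourable for the real genotype contrasts, above all over both oxygen conditions.

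The alternatives tried were the fit without the set, the set as a random block, fits of only the 2 groups compared, quantile normalization, median centring, no filter and a filter at the 50th percentile, the mean of a gene's probe sets, every probe set on its own, eBayes without a trend or with robust settings, leaving out each array in turn, a minimum change of 2-fold with and without the test, an additive fit, scores of macrophage or muscle markers as covariates, and the mean of normoxia and hypoxia per genotype and set.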

Results

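The samples were fibroblasts isolated from mouse embryos of the C57BL/6J strain. Wild-type cells and cells lacking Hif-p4h-1 were compared under normoxia and under hypoxia. Hif-p4h-1 is the enzyme encoded by Egln2, one of the prolyl hydroxylases that mark the alpha subunits of hypoxia-inducible factor (HIF) for degradation when oxygen is present. The oxygen level and the length of the hypoxic exposure are not given in the sources used here. Each of the 4 groups had 2 arrays, 1 in each of 2 sets. The first principal component, with 54.1% of the variance, separated the sets, and the second, with 25.7%, separated hypoxia from normoxia. Pearson's r between the 2 arrays of a group lay between 0.983 and 0.989 across genes, and between arrays of different groups in the same set between 0.983 and 0.998.

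Egln2, the targeted gene, was read by 1 probe set. Its log2 value in normoxia was 8.84 and 9.07 in the 2 wild-type arrays and 8.0 and 8.34 in the 2 knockout arrays. In hypoxia it was 8.95 and 9.13 in wild type and 8.66 and 8.85 in knockout. In normoxia it was lower in the knockout by -0.79 ± 0.089 on the log2 scale (SE, n = 2 per group, adjusted p = 0.0489). In hypoxia the difference of -0.29 ± 0.089 did not pass (adjusted p = 0.725). Egln2 rose with hypoxia in the knockout by 0.59 ± 0.089 (adjusted p = 0.00919), with 0.09 ± 0.089 in wild type (adjusted p = 0.575), and the interaction of 0.50 did not pass (adjusted p = 1). Signal remained in the knockout, and the sources used here do not say whether the probe set lies in the deleted part, so these values check the labels only in part. The direction held in 4 of 4 pairs of arrays of the same set, but the normoxic call was lost in each of the 8 fits that left out 1 array, with adjusted p from 0.104 to 0.539.

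The other members of the HIF hydroxylase and HIF subunit group that were followed did not differ by genotype in any contrast. Egln1, which encodes the main oxygen-sensing HIF hydroxylase, rose with hypoxia by 1.23 ± 0.099 in wild type (adjusted p = 5.4e-04) and by 1.16 ± 0.099 in knockout (adjusted p = 0.0011). Egln3 rose by 3.42 ± 0.28 in wild type (adjusted p = 5.9e-04) and by 3.07 ± 0.28 in knockout (adjusted p = 0.00154). Hif1a differed between hypoxia and normoxia by -0.12 over both genotypes and was not called (adjusted p = 0.064). A weaker probe set of Epas1, which encodes the HIF-2 alpha subunit, changed little. It read 5.28 and 5.46 in normoxic and 5.39 and 4.81 in hypoxic wild type. In knockout it read 5.13 and 5.32 in normoxia and 5.08 in both hypoxic arrays. By the probe set used in the tests, Epas1 fell over both genotypes by 0.91 ± 0.19 (adjusted p = 0.00861), with -0.49 in the first set and -1.32 in the second. Arnt, which encodes the shared beta subunit, fell by 0.24 ± 0.071 (adjusted p = 0.0356), a call that 1 of the 8 fits without 1 array kept.

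**Figure D1:**
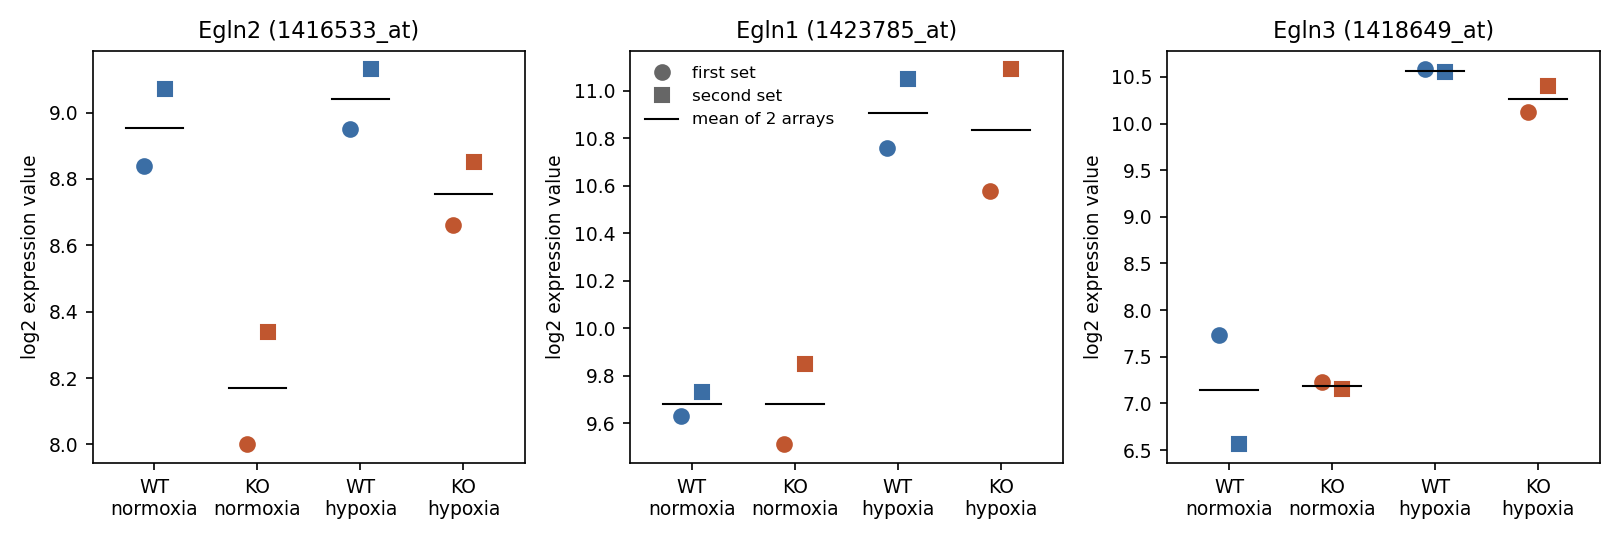
Log2 expression value (vertical axis) of Egln2, Egln1 and Egln3 in each of the 8 arrays by group, with circles for the first set, squares for the second and lines for the mean of 2 arrays. Egln2 lies at 8.0 and 8.34 in the normoxic knockout arrays and between 8.66 and 9.13 in the 6 others.

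The first comparison asked what hypoxia changes in wild-type fibroblasts. Genes of HIF signalling and of anaerobic glucose use rose. The largest rises were those of Ankrd37 at 4.17 ± 0.14 on the log2 scale (SE, n = 2 per group), of Bnip3, a mitophagy receptor, at 3.95 ± 0.085, and of Pdk1, a kinase that closes the pyruvate dehydrogenase step, at 3.80 ± 0.098. Their adjusted p were 4.1e-06, 4.0e-07 and 9.3e-07. Slc16a3, a lactate exporter, rose by 3.34 ± 0.19 and Car9, a carbonic anhydrase of the cell surface, by 2.88 ± 0.18. Egln3, Mgarp (3.09), Prelid2 (3.00) and Tafa2 (2.86) made up the named rises, and a further probe set of Prelid2 gave 0.09 (adjusted p = 0.778).

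The largest falls in wild type were smaller than the largest rises. Neat1, the long noncoding RNA of nuclear paraspeckles, fell by 1.91 ± 0.28 (adjusted p = 0.00504). Srpx fell by 1.64 ± 0.23, Wdr5b by 1.64 ± 0.20 and Nipal4 by 1.54 ± 0.39, a call kept in 2 of the 8 fits without 1 array and down to -1.02. Msr1, a scavenger receptor of macrophages, fell by 1.51 ± 0.35, with -2.26 in the first set and -0.75 in the second, and was not called without wild-type normoxia replicate 1 (-0.83). H3f3b, Rfx5 (a regulator of class II major histocompatibility genes), Syt14, Trpc2 and Ucn2 fell by 1.49, 1.36, 1.31, 1.30 and 1.30. Further probe sets gave -0.18 each for Neat1 and Nipal4, -0.39 and -0.83 for Msr1 and -0.87 for Trpc2, and none of these was called. In all, 2237 of 13647 genes were called, 1029 higher and 1208 lower, and all of them had the same direction in both sets. Of these, 118 rose and 40 fell by at least 2-fold.

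Of the 46 HIF target genes tested in wild type, 40 rose, none fell and 6 did not pass, and 42 rose when adjusted over the list alone. Their median change was 1.22, with 1.20 in the first set and 1.22 in the second (camera adjusted p = 4.0e-40). This call was kept, at adjusted p = 0.0287 with an estimated correlation. Fam162a (2.12 ± 0.063) and Slc2a1, the main glucose transporter of fibroblasts (1.88 ± 0.065), were among the members with the smallest p. Of the 18 glycolysis genes 15 rose and 3 did not pass, the same as when adjusted over the list alone, with a median of 1.22 (camera adjusted p = 1.1e-19, and adjusted p = 0.112 with an estimated correlation). Pfkl, a phosphofructokinase subunit, rose by 2.46 ± 0.10, Aldoa by 1.33 ± 0.065 and Ldha, which makes lactate, by 1.21 ± 0.055.

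Genes of respiration and of the p53 response were lower as groups in wild type at the preset correlation, although most members did not pass. Of 34 genes of oxidative phosphorylation and the TCA cycle, 12 fell, 1 rose and 21 did not pass, and adjusted over the list alone 12 fell and 2 rose. Their median was -0.13 (camera adjusted p = 0.00729, and adjusted p = 0.753 with an estimated correlation). The call was kept in 7 of the 8 fits without 1 array, with a median down to -0.0733. Atp5a1 of the ATP synthase fell by 0.71 ± 0.059 and Sdha of complex II by 0.67 ± 0.083. Of 36 p53 target genes, 12 fell, none rose and 24 did not pass, and adjusted over the list alone 17 fell and 1 rose. Their median was -0.32 (camera adjusted p = 2.1e-06, and adjusted p = 0.731 with an estimated correlation). Btg2, an inhibitor of proliferation, fell by 0.98 ± 0.10, Eda2r by 0.98 ± 0.12, Aen, an apoptosis-enhancing nuclease, by 0.92 ± 0.11 and Plk2 by 0.63 ± 0.070.

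The matrix, myofibroblast, ATF4 and interferon lists were also lower as groups in wild type at the preset correlation. Of 40 collagen and fibrillar matrix genes 6 fell, 1 rose and 33 did not pass, and adjusted over the list alone 7 fell and 1 rose (median -0.20, camera adjusted p = 0.00875, and adjusted p = 0.731 with an estimated correlation). Ogn fell by 0.79 ± 0.11. Among 31 myofibroblast and TGF-beta genes 6 fell, 1 rose and 24 did not pass, and adjusted over the list alone 10 fell and 1 rose (median -0.18, camera adjusted p = 0.00468, and adjusted p = 0.77 with an estimated correlation). Tgfb2 fell by 0.97 ± 0.11. Of 36 genes of the ATF4 and unfolded protein response 12 fell, 5 rose and 19 did not pass, and adjusted over the list alone 14 fell and 5 rose (median -0.19, camera adjusted p = 0.00875, and adjusted p = 0.334 with an estimated correlation). Vldlr, a lipoprotein receptor, rose by 1.5 ± 0.089, while Ddit3 fell by 0.80 ± 0.094 and the chaperones Pdia6 and Calr fell by 0.66 and 0.55. Of 34 interferon response genes 8 fell, 1 rose and 25 did not pass, and adjusted over the list alone 14 fell and 1 rose (median -0.38, camera adjusted p = 2.6e-04, and adjusted p = 0.731 with an estimated correlation). Usp18 fell by 1.21 ± 0.20, whereas Ifi204 rose by 1.80 ± 0.22. The interferon list stood at -0.42 and -0.21 in the sets, and the macrophage and leukocyte markers moved beside it at -0.47 and -0.19 (median -0.33, 18 of 22 negative, adjusted p = 0.123, not called). Without wild-type normoxia replicate 1 the interferon median was -0.23, and without wild-type hypoxia replicate 2 the ATF4 median was -0.11, both still called. Without wild-type hypoxia replicate 1 the matrix and myofibroblast lists were not called, at -0.0942 and -0.0833, nor was the latter without wild-type normoxia replicate 2.

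Besides HIF target genes and glycolysis, cholesterol synthesis rose in wild type, with 3 of 20 genes up and 17 not passed, over all genes and adjusted over the list alone alike. Its median was 0.19 (camera adjusted p = 0.0148, and adjusted p = 0.77 with an estimated correlation), with 0.51 in the first set and -0.12 in the second. It was not called without normoxia or hypoxia replicate 1 of wild type, at 0.0817 and -0.0892. Stard4 rose by 0.73 ± 0.13 and Sqle by 0.74 ± 0.18, each called in 5 of the 8 fits without 1 array, with Sqle down to 0.42. NF-kB target genes were not called as a group, with a median of 0 and an adjusted p of 0.551. Of their 36 members, Ptgs2 (0.65 ± 0.11) and Ier3 (0.59 ± 0.10) were among 4 that rose and Tnip1 (-0.44 ± 0.10) and Ccl20 (-0.55 ± 0.13) among 3 that fell, against 5 and 3 when adjusted over the list alone. The RNA controls of the arrays differed with oxygen too. The log2 difference between the 3′ and 5′ control probe sets of Actb was higher in hypoxia in 4 of 4 pairs of arrays, by 0.10 to 0.17, and that of Gapdh in 4 of 4, by 0.04 to 0.33. Without the set in the fit, 20 genes were called, all 20 of them among the 2237, with the set as a random block 1133, and in a fit of the wild-type arrays alone 487. Leaving out 1 wild-type array gave 490 without hypoxia replicate 1, 551 without normoxia replicate 1, 817 without normoxia replicate 2 and 1223 without hypoxia replicate 2.

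**Figure D2:**
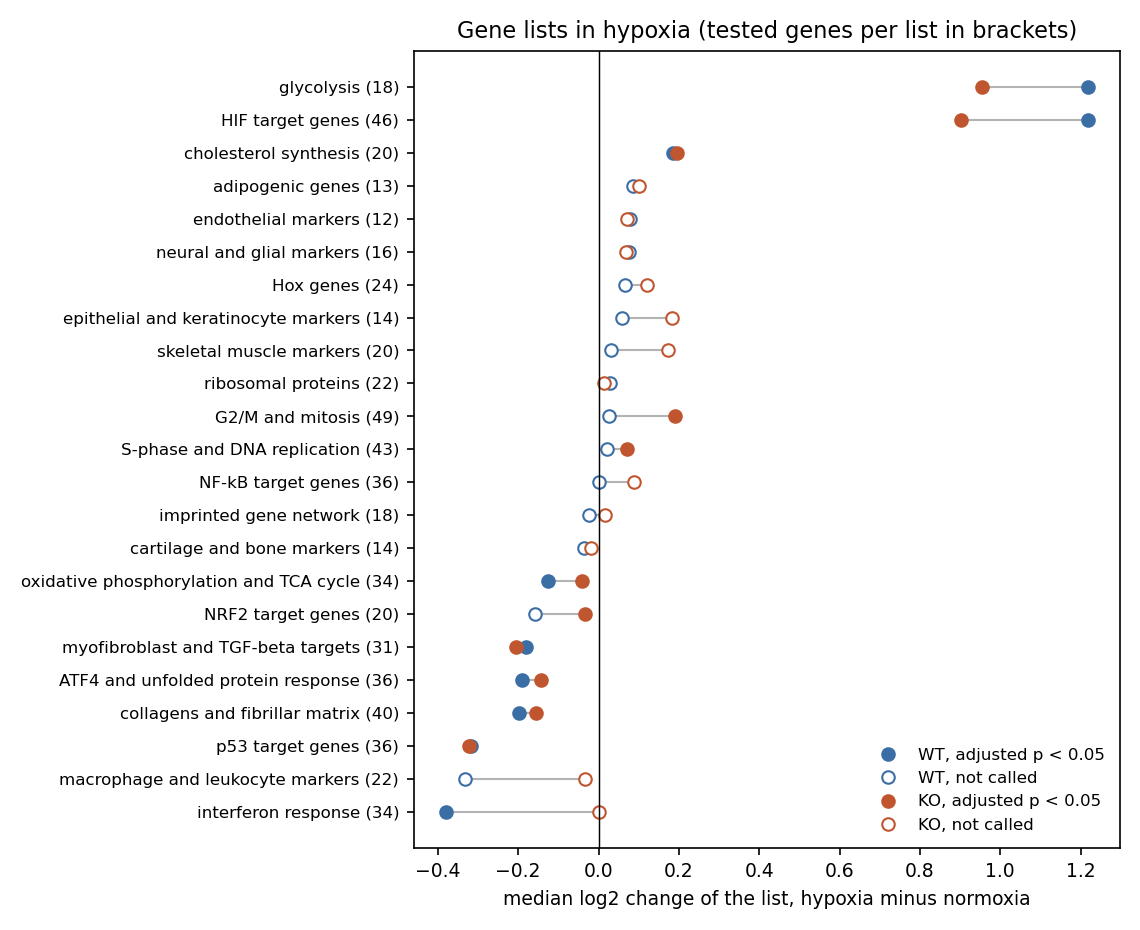
Median log2 change from normoxia to hypoxia (horizontal axis) of the tested genes of each of 23 gene lists, in wild type (blue) and knockout (orange), filled where the list's camera adjusted p at the preset correlation passed. HIF target genes had a median of 1.22 in wild type and 0.90 in knockout, and p53 target genes of -0.32 in both.

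The second comparison asked the same of the knockout fibroblasts. Ankrd37 rose by 3.28 ± 0.14, Egln3 by 3.07 ± 0.28, Bnip3 by 3.05 ± 0.085, Car9 by 2.93 ± 0.18 and Pdk1 by 2.90 ± 0.098 (SE, n = 2 per group, adjusted p = 2.7e-05, 0.00154, 3.2e-06, 1.4e-04 and 5.7e-06). Mgarp (2.82), Pygl (2.42), a glycogen phosphorylase, Slc16a3 (2.42), Prelid2 (2.31) and the secreted glycoprotein gene Stc1 (2.25) followed. Neat1 fell by 1.85 ± 0.28, Wdr5b by 1.43 ± 0.20, the imprinted noncoding RNA Meg3 by 1.41 ± 0.19 and Snhg14 by 1.39 ± 0.14. Ankrd28, H3f3b, Srpx and Ercc6 fell by 1.38, 1.29, 1.26 and 1.20. Taf15 fell by 1.23, and a further probe set of it gave 0.60 (adjusted p = 0.0861). Further probe sets of Prelid2 (0.17), Stc1 (0.29), Neat1 (-0.04) and Ankrd28 (-0.34) were not called either.

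In the knockout, 1380 genes were called, 680 higher and 700 lower, all with the same direction in both sets, and 83 rose and 24 fell by at least 2-fold. Of the 46 HIF target genes 39 rose and 7 did not pass, and adjusted over the list alone 41 rose and 1 fell (median 0.90, 0.84 in the first set and 0.92 in the second, camera adjusted p = 1.3e-35, and adjusted p = 0.0343 with an estimated correlation). Glycolysis had 15 of 18 genes up, as when adjusted over the list alone, with a median of 0.96 (camera adjusted p = 8.6e-20, and adjusted p = 0.111 with an estimated correlation). Tpi1 rose by 1.38 ± 0.078 and Ldha by 0.88 ± 0.055. Of 36 p53 target genes 10 fell, none rose and 26 did not pass, and adjusted over the list alone 16 fell and 1 rose (median -0.32, camera adjusted p = 5.3e-06, and adjusted p = 0.681 with an estimated correlation). Plk2 fell by 0.69 ± 0.070, Aen by 0.69 ± 0.11 and Btg2 by 0.61 ± 0.10. Without knockout hypoxia replicate 2 the median of the p53 list was -0.17, still called.

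Further lists passed in the knockout at the preset correlation only. Respiration and TCA cycle genes fell, with 6 down, 1 up and 27 not passed, against 9 down and 1 up when adjusted over the list alone (median -0.04, adjusted p = 0.0294, and adjusted p = 0.717 with an estimated correlation). Myofibroblast and TGF-beta genes fell, with 5 down of 31 and 6 when adjusted over the list alone (median -0.21, adjusted p = 8.2e-04, and adjusted p = 0.681 with an estimated correlation), among them Tgfb2 at -1.09 ± 0.11. Collagens and fibrillar matrix fell, with 3 down of 40, as when adjusted over the list alone (median -0.16, adjusted p = 0.0154, and adjusted p = 0.681 with an estimated correlation). In the ATF4 and unfolded protein response list 8 of 36 fell, 3 rose and 25 did not pass, and adjusted over the list alone 14 fell and 4 rose (median -0.14, adjusted p = 0.00621, and adjusted p = 0.286 with an estimated correlation). NRF2 target genes fell, with 3 down of 20, against 7 down and 1 up when adjusted over the list alone (median -0.03, adjusted p = 0.0459, and adjusted p = 0.681 with an estimated correlation). Cholesterol synthesis rose, with 2 up of 20 and 3 when adjusted over the list alone (median 0.20, adjusted p = 0.0294, and adjusted p = 0.859 with an estimated correlation), at 0.45 in the first set and 0.005 in the second. Of the 8 fits without 1 array, 6 kept the calls of the respiration, matrix, NRF2 and cholesterol lists and 7 that of the myofibroblast list. Cholesterol synthesis stood at -0.0258 and NRF2 at -0.02 without knockout normoxia replicate 1, respiration at 0.0075 without knockout normoxia replicate 2, and matrix and myofibroblast genes at -0.0633 and -0.0867 without knockout hypoxia replicate 2. Other fits moved medians away from 0. NRF2 stood at -0.235 without knockout hypoxia replicate 1 and at -0.192 without knockout normoxia replicate 2. Cholesterol synthesis stood at 0.416 without the latter, and respiration at -0.0833 without knockout normoxia replicate 1.

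Cell cycle genes rose as groups in the knockout at the preset correlation. G2/M and mitosis genes had 6 of 49 up, 2 down and 41 not passed, and adjusted over the list alone 12 up and 3 down (median 0.19, adjusted p = 0.00153, and adjusted p = 0.76 with an estimated correlation), with 0.05 in the first set and 0.38 in the second. Plk1, a mitotic kinase, rose by 0.67 ± 0.12, and Cdk1, the main mitotic cyclin-dependent kinase, fell by 0.38 ± 0.072. S-phase genes had 4 of 43 up and 6 when adjusted over the list alone (median 0.07, adjusted p = 0.0492, and adjusted p = 0.681 with an estimated correlation), with Mcm3, a subunit of the replicative helicase, at 0.73 ± 0.086. Both cell cycle calls were kept in 6 of the 8 fits without 1 array. The G2/M median was 0.0567 without knockout hypoxia replicate 2 and 0.372 without knockout hypoxia replicate 1. The S-phase median was 0.113 without knockout normoxia replicate 2. NF-kB target genes were not called (median 0.09, adjusted p = 0.469), with 3 members up and 1 down over all genes and 3 up and 2 down when adjusted over the list alone. Without the set 12 genes were called, with the set as a random block 517, and in a fit of the knockout arrays alone 53. Leaving out 1 knockout array gave 121 without normoxia replicate 2, 131 without hypoxia replicate 2, 147 without normoxia replicate 1 and 525 without hypoxia replicate 1.

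The hypoxia responses of wild type and knockout were then set side by side. The calls shared 552 rising and 611 falling genes, where 51.3 and 62.0 would be shared by independent lists, and 0 of the 1163 genes called in both went in opposite directions. Pearson's r of the log2 changes was 0.839 and Spearman's rho 0.750 across 13647 genes, which are not independent replicates, and the contrasts share no array. Of the 2454 genes called in either, 2430 had the same sign in both and 1804 had the larger change in wild type, with a slope of knockout on wild type of 0.809. These genes were chosen by the same changes, and more were called in wild type. The count and the slope thus lean toward a smaller knockout response. For 3875 genes called over both genotypes, outside the HIF and glycolysis lists, a ratio that treats the genotypes alike was 0.882. It was 0.807 in the first set and 0.959 in the second.

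The interaction asked whether loss of Hif-p4h-1 changes the hypoxia response. By limma, 0 of 13647 genes were called, and 329 had an unadjusted p under 0.05. These 329 are a smaller share than the 0.05 given where nothing changes, so the interaction test may have been too strict. Its 0 calls therefore do not show that the responses were equal. The 46 HIF target genes had a median interaction of -0.25, with -0.26 in the first set and -0.30 in the second, and 39 of them were negative. As a group they were lower than other genes (camera adjusted p = 8.7e-22), which was not kept at adjusted p = 0.0712 with an estimated correlation. Over all genes none passed, and 11 were lower when adjusted over the list alone, among them Bnip3 at -0.90 ± 0.12. Glycolysis had a median of -0.16, with 5 of 18 lower when adjusted over the list alone, among them Pfkl at -0.59 ± 0.15 (camera adjusted p = 1.4e-09, and adjusted p = 0.308 with an estimated correlation). G2/M and mitosis genes had a median interaction of 0.15 and interferon response genes of 0.24 (camera adjusted p = 6.2e-07 and 7.7e-07, and adjusted p = 0.951 and adjusted p = 0.802 with an estimated correlation), with 0 and 1 members higher when adjusted over the list alone. The macrophage markers, described with the genotype comparisons, had a median interaction of 0.33 (camera adjusted p = 0.0185, and adjusted p = 0.951 with an estimated correlation), with no member passing when adjusted over the list alone. This median turned negative without normoxia replicate 1 of either genotype, at -0.085 for wild type and -0.0917 for knockout, and its call was kept in 4 of the 8 fits without 1 array. The glycolysis call was kept in all 8, with -0.095 without wild-type normoxia replicate 2. The G2/M call was kept in 5, with 0.0167 without knockout hypoxia replicate 2, and the interferon call in 7, with 0.12 without wild-type normoxia replicate 1. The p53 and NF-kB target genes had medians of 0.07 and -0.04 and were not called (adjusted p = 0.201 and 0.949).

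**Figure D3:**
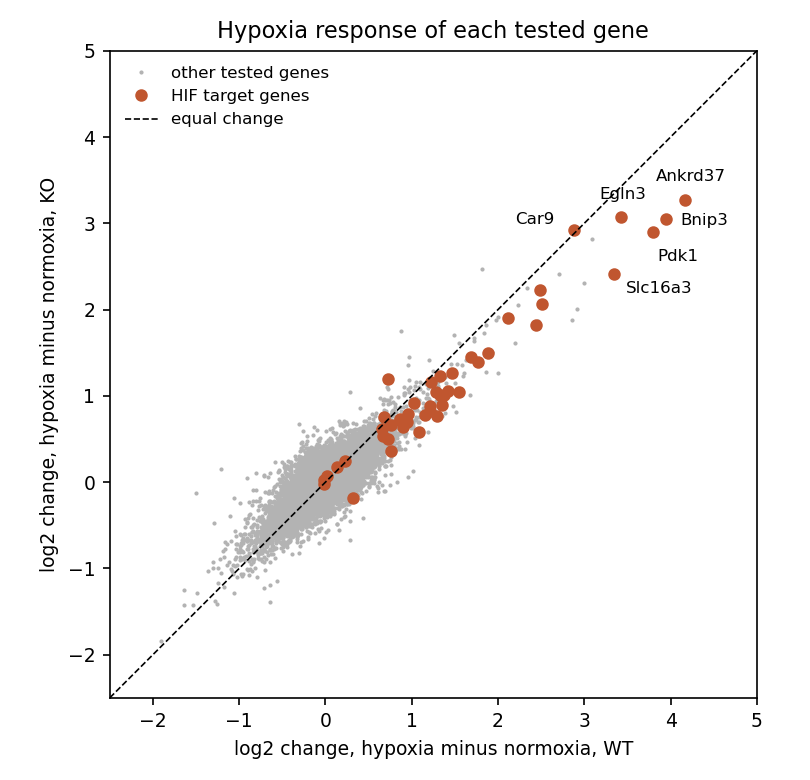
Log2 change from normoxia to hypoxia of each of 13647 genes in wild type (horizontal axis) and knockout (vertical axis), with HIF target genes in orange and a dashed line at equal change. Bnip3 lies at 3.95 and 3.05 and Pdk1 at 3.80 and 2.90, below the line, and Car9 at 2.88 and 2.93, close to it.

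Over both genotypes, 3922 genes changed with hypoxia, 1854 higher and 2068 lower. Ankrd37 (3.72 ± 0.10), Bnip3 (3.50 ± 0.060), Pdk1 (3.35 ± 0.070), Egln3 (3.25 ± 0.20) and Mgarp (2.96 ± 0.12) rose most, and Neat1 (-1.88 ± 0.20), Wdr5b (-1.53 ± 0.14), Nipal4 (-1.48 ± 0.28), Srpx (-1.45 ± 0.17) and H3f3b (-1.39 ± 0.18) fell most (SE, n = 4 arrays against 4 in the limma fit). HIF target genes rose, with 41 of 46 up and 42 when adjusted over the list alone (median 1.04, camera adjusted p = 2.1e-33, and adjusted p = 0.0377 with an estimated correlation). Of 36 p53 target genes 22 fell, 1 rose and 13 did not pass, and adjusted over the list alone 23 fell and 4 rose (median -0.34, camera adjusted p = 1.7e-06, and adjusted p = 0.693 with an estimated correlation). NF-kB target genes were again not called as a group (median 0.02, adjusted p = 0.476), while 7 of 36 rose and 4 fell, and 8 rose and 5 fell when adjusted over the list alone. Ccl2, a monocyte chemokine, rose by 0.48 ± 0.082 and Nfkbia, the inhibitor of NF-kB, by 0.25 ± 0.043. Without the set 99 genes were called, and without knockout normoxia replicate 1 or knockout hypoxia replicate 2 there were 2554 and 2588.

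The next comparison asked what loss of Hif-p4h-1 changes in normoxia. By limma 5 genes were called, 1 higher and 4 lower, and 914 had an unadjusted p under 0.05. Bnip3 was higher in the knockout by 0.83 ± 0.085 (SE, n = 2 per group, adjusted p = 0.0273), with 0.90 in the first set and 0.76 in the second. Pf4, a chemokine made by platelets and macrophages, fell by 1.48 ± 0.13 (adjusted p = 0.0124), the lysozyme genes Lyz1 and Lyz2 by 1.47 ± 0.10 and 1.33 ± 0.099 (adjusted p = 0.00472 and 0.0049), and Egln2 was the fourth. Lyz1 and Lyz2 are near-identical copies whose probes may read both, so their separate values are uncertain. The 22 macrophage and leukocyte markers tested were all lower in the knockout, with a median of -1.34, at -1.99 in the first set and -0.77 in the second. Of these, 2 fell over all genes and 18 when adjusted over the list alone (camera adjusted p = 7.1e-29, and adjusted p = 0.304 with an estimated correlation). The 20 skeletal muscle markers had a median of -1.27, at -2.70 in the first set and 0.25 in the second, with no member passing either way (camera adjusted p = 1.0e-04, and adjusted p = 0.598 with an estimated correlation).

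Beside these markers of other cell types, smaller shifts passed in normoxia at the preset correlation. HIF target genes were higher in the knockout with a median of 0.12 (0.15 and 0.17 in the sets, camera adjusted p = 2.0e-09, and adjusted p = 0.252 with an estimated correlation), with 1 of 46 up over all genes and 11 when adjusted over the list alone. Pdk1 stood at 0.76 ± 0.098 (adjusted p = 0.0524). Glycolysis was higher with a median of 0.12 and 5 of 18 up when adjusted over the list alone and none over all genes (camera adjusted p = 5.2e-06, and adjusted p = 0.304 with an estimated correlation). Lists with lower values and no member passing over all genes were interferon response (-0.33, 5 of 34 lower when adjusted over the list alone), G2/M and mitosis (-0.18), S-phase (-0.12), imprinted genes (-0.14, 1 of 18 lower when adjusted over the list alone) and the ATF4 and unfolded protein response (-0.08). Their camera adjusted p were 9.7e-08, 8.3e-09, 5.2e-06, 0.0265 and 0.0265, and with an estimated correlation adjusted p = 0.347, 0.598, 0.304, 0.429 and 0.304. Interferon response genes moved with the macrophage markers by set, at -0.49 and -0.14. The p53 target genes (0.12, at 0.19 in the first set and 0.05 in the second) and the myofibroblast genes (0.12, at 0.21 and 0.02) were higher as groups with no member passing either way (camera adjusted p = 8.0e-06 and 1.0e-04, and adjusted p = 0.598 for each with an estimated correlation). NF-kB target genes did not differ as a group (median -0.05, adjusted p = 0.538) and had no member passing either way. No gene was called without the set in the fit (143 with an unadjusted p under 0.05), with the set as a random block (607) or in a fit of only the normoxic arrays (707). Leaving out 1 array gave 0 to 3 genes, with 0 without knockout normoxia replicate 1 or wild-type normoxia replicate 2 and 1 without their counterparts, and Bnip3 was kept in none of these fits, Lyz1 in 5 and Pf4 and Lyz2 in 4 each. Without normoxia replicate 1 of wild type or knockout the muscle list stood at -0.147 and -0.248 and the imprinted list at -0.0583 and -0.045, and neither was called. The myofibroblast call was lost without knockout normoxia replicate 1 (0.0367), the G2/M call without knockout normoxia replicate 2 (-0.102) and the ATF4 call without normoxia replicate 2 of either genotype (-0.0442 for wild type), and the interferon median was -0.122 without wild-type normoxia replicate 1. Still called, the glycolysis median ranged from 0.0675 without wild-type normoxia replicate 2 to 0.203 without wild-type normoxia replicate 1, and without the latter the G2/M and myofibroblast medians were -0.0817 and 0.0533.

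In hypoxia, 4 genes were called by limma between knockout and wild type, all lower, and 753 had an unadjusted p under 0.05. Pf4 fell by 1.47 ± 0.13, Lyz1 by 1.07 ± 0.10 and Lyz2 by 1.06 ± 0.099 (SE, n = 2 per group, adjusted p = 0.0194 each), and Itga6, the integrin alpha 6 chain, by 0.91 ± 0.098 (adjusted p = 0.0403). Macrophage and leukocyte markers again had lower values, with a median of -1.11, at -1.63 in the first set and -0.74 in the second. Of 22, 2 fell over all genes and 16 when adjusted over the list alone (camera adjusted p = 1.2e-24, and adjusted p = 0.537 with an estimated correlation). Muscle markers had a median of -1.07, at -2.33 in the first set and 0.24 in the second (camera adjusted p = 7.6e-04, and adjusted p = 0.665 with an estimated correlation), with no member passing either way. HIF target genes were lower as a group by -0.12 (camera adjusted p = 8.5e-05, and adjusted p = 0.537 with an estimated correlation), with none passing over all genes and Selenbp1 (-0.92 ± 0.16) when adjusted over the list alone. The p53 target genes were higher with a median of 0.21, at 0.44 in the first set and 0.06 in the second, none over all genes and 5 of 36 when adjusted over the list alone, among them Btg2 at 0.46 ± 0.10 and Sesn2 at 0.43 ± 0.10 (camera adjusted p = 3.5e-10, and adjusted p = 0.665 with an estimated correlation). Myofibroblast genes were higher with a median of 0.08, at 0.24 in the first set and -0.02 in the second, and no member passing either way (camera adjusted p = 5.7e-04, and adjusted p = 0.665 with an estimated correlation). NF-kB target genes were not called (median -0.02, adjusted p = 0.547) and had no member passing either way. Without wild-type hypoxia replicate 1 the medians of the muscle and myofibroblast lists were -0.01 and -0.00167, and without knockout hypoxia replicate 1 -0.0942 and 0.0117, and neither list was called. In these 2 fits the p53 median was 0.101 and 0.0933, still called, and that of HIF target genes without knockout hypoxia replicate 1 was -0.0667, still called. No gene was called without the set (134 with an unadjusted p under 0.05), with a random block (543) or in a fit of only the hypoxic arrays (488). Of the fits without 1 array, 7 called 0 genes and that without knockout normoxia replicate 2 called 5, so Pf4, Lyz1 and Lyz2 were kept in 1 fit each and Itga6 in none.

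The genotype contrasts shared 3 of their 4 falling genes each, Pf4, Lyz1 and Lyz2. Pearson's r of their log2 changes was 0.555 and Spearman's rho 0.322 across genes. They share no array, but the normoxic and hypoxic arrays of one genotype and set deviate together, so this overlap is not independent support for an effect of the genotype. The interaction, which tests the difference of these contrasts, called 0 genes, but that test may have been too strict.

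Over both oxygen conditions, 35 genes differed between knockout and wild type, 8 higher and 27 lower, and 17 fell by at least 2-fold. These calls treat the normoxic and hypoxic arrays of one genotype and set as separate values, although they deviate together, and with their mean as 1 value, 2 against 2, no gene was called (602 with an unadjusted p under 0.05), in a fit with 1 residual degree of freedom. Egln2 was lower by -0.54 ± 0.063 (adjusted p = 0.0225), a call kept in none of the 8 fits without 1 array. The largest falls were those of Gpm6a, a neuronal membrane glycoprotein, at -1.99 ± 0.24 (SE, n = 4 arrays against 4, adjusted p = 0.0225), and of the leukocyte genes Laptm5 (-1.87 ± 0.24), Lcp1 (-1.74 ± 0.22), Tyrobp (-1.67 ± 0.20) and Fermt3 (-1.63 ± 0.15). Lhx9 and Eya1, which encode developmental transcriptional regulators, rose by 0.83 ± 0.086 and 0.78 ± 0.090, Sorbs2 by 0.79 ± 0.097, Col2a1, the main cartilage collagen, by 0.74 ± 0.073 and the chloride channel gene Ano1 by 0.63 ± 0.090. Apart from Laptm5 and Fermt3, kept in 3, these 10 genes were called in 1 or 2 of the 8 fits without 1 array. None of their further probe sets was called, with -0.93 for Gpm6a, -0.66 for Lcp1, -0.33 and -0.04 for Fermt3, 1.06 and 0.36 for Lhx9, 0.12 for Eya1 and 0.36 for Ano1. Those of Laptm5 gave -0.59, -0.52 and 0.08 and those of Sorbs2 0.16 and -0.20, so 1 each had the opposite sign. Macrophage and leukocyte markers fell, with 9 of 22 down over all genes and 20 when adjusted over the list alone (median -1.26, at -1.73 in the first set and -0.82 in the second, camera adjusted p = 2.2e-30, and adjusted p = 0.53 with an estimated correlation). Lyz1 (-1.27 ± 0.071) and Lyz2 (-1.19 ± 0.070) were the members called in all 8 fits without 1 array, and Csf1r, the receptor for macrophage colony-stimulating factor, stood at -1.37 ± 0.14 (adjusted p = 0.0137). Matrix genes were not called as a group (median -0.04, adjusted p = 0.0685), while Dcn (-0.51 ± 0.061) and Fbn2 (-0.43 ± 0.056) fell and Ogn (0.58 ± 0.077) rose, against 8 down and 3 up when adjusted over the list alone.

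In the same contrast p53 target genes were higher with a median of 0.17, at 0.27 in the first set and 0.07 in the second, none over all genes and 10 up and 1 down of 36 when adjusted over the list alone (camera adjusted p = 1.7e-10, and adjusted p = 0.53 with an estimated correlation). Perp, an effector of p53-dependent apoptosis, stood at 1.06 ± 0.20 (adjusted p = 0.0998) and Fas at 0.63 ± 0.12 (adjusted p = 0.115). The muscle markers, with a median of -1.12, stood at -2.51 and 0.24 in the sets, had a median of -0.59 without wild-type normoxia replicate 1, and no member passed either way (camera adjusted p = 1.6e-05, and adjusted p = 0.556 with an estimated correlation). NF-kB target genes were not called (median -0.06, adjusted p = 0.50) and had no member passing either way. Without the set, and with the set as a random block, no gene was called (243 and 938 with an unadjusted p under 0.05). Leaving out 1 array gave 58 genes without wild-type normoxia replicate 2, 15 and 8 without knockout normoxia replicates 2 and 1, and 3 or 4 without any of the other 5 arrays.

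**Figure D4:**
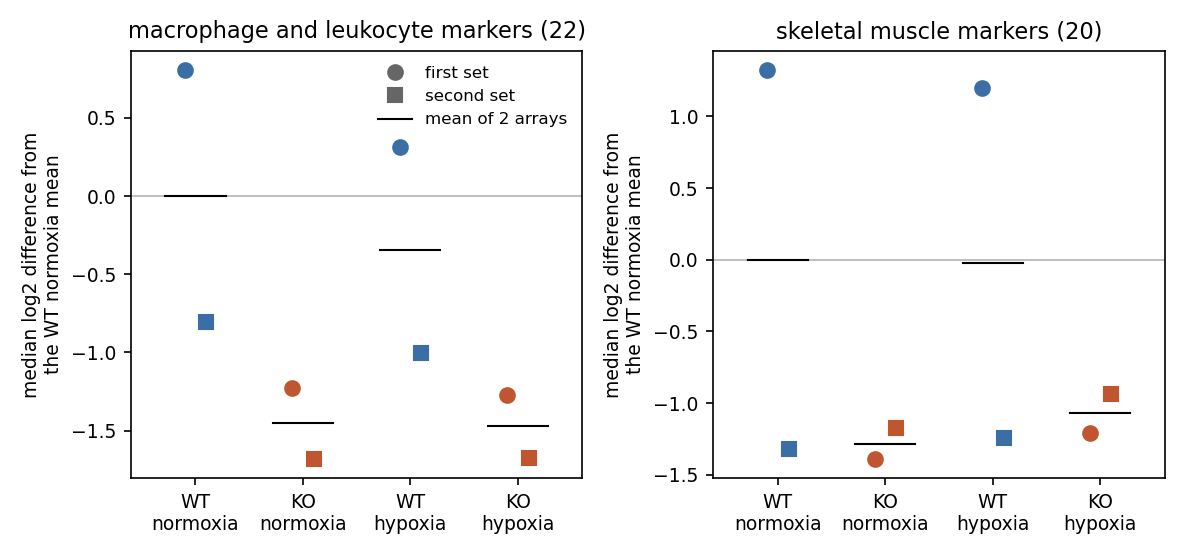
Median log2 difference from the wild-type normoxia mean (vertical axis) over 22 macrophage and leukocyte markers and 20 skeletal muscle markers in each array by group, with circles for the first set, squares for the second and lines for the mean of 2 arrays. All knockout arrays lie at or below -1.23 for macrophage markers, with wild type at 0.81 and 0.32 in the first set and at -0.81 and -1.0 in the second, while for muscle markers the wild-type arrays of the second set, at -1.32 and -1.25, lie below its knockout arrays, at -1.18 and -0.93.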

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

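The tests on macrophage and muscle markers and the comparison of the sets for HIF target genes were chosen after the result was seen, as were the sign tests and the other rules on spread by which values were judged, while the splits of the arrays and the tests of a signal ceiling and of a weaker exposure were fixed earlier. The hypoxia response differed between knockout and wild type in 5 gene lists by the interaction test at the preset correlation, and in none with an estimated correlation. The median interactions were -0.25 for HIF target genes, -0.16 for glycolysis, 0.15 for G2/M and mitosis genes, 0.24 for interferon response genes and 0.325 for macrophage and leukocyte markers. With an estimated correlation their adjusted p were 0.0712, 0.308, 0.951, 0.802 and 0.951. For single genes the interaction called 0 by limma, with 329 at an unadjusted p under 0.05, a smaller share than where nothing changes. That test may thus have been too strict.

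As a group at the preset correlation HIF target genes rose less with hypoxia in the knockout, with 39 of 46 interactions negative, though none passed over all genes and the group call was lost at an adjusted p of 0.0712 with an estimated correlation. In the first and second set 39 and 38 of the 46 interactions were negative (sign test widened by the estimated correlation, p = 7.7e-04 and 0.00166). The direction was thus shared by both sets. Each set holds 1 array per group, so these p-values measure the spread over genes and not between arrays. The smaller of the set medians, -0.255, also lies within the SD of its members of 0.306, and only 33 and 30 were below -0.1. Variation between single arrays was therefore not excluded. For a signal ceiling, the 24 members with a highest group mean under 10 had a median of -0.25. This median met the bound fixed earlier against a ceiling. The explanation still stays open, since their SD was 0.313 and the 18 negative ones did not pass the same sign test, a rule chosen later. A weaker hypoxic exposure of the knockout cultures could act only on the part of the difference that arose in hypoxia. Knockout minus wild type, the list median was 0.12 in normoxia and -0.12 in hypoxia. For the hypoxic part such an exposure stays open. In the first set the ratio of the knockout to the wild-type response was 0.807 for HIF target genes. It was 0.807 as well for the 3875 other genes changed by hypoxia, a difference of -0.000534. In the second set the ratios were 0.816 and 0.959, a difference of 0.142. These ratios take in the normoxic values too, so they do not separate the parts. An effect of losing Hif-p4h-1, through the higher normoxic start of Bnip3 or in hypoxia itself, also stays open and was not tested.

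Macrophage and leukocyte markers were lower in the knockout in all 22 genes tested (camera adjusted p = 2.2e-30, and adjusted p = 0.53 with an estimated correlation), a list that shares no gene with another list. The fall was not that of 1 set alone, since the smaller fall of the set medians was -0.8175 (SD of the markers in that set 0.465). Each set holds every group once, so a shift between the sets could not produce it, and this says nothing about other causes. The 2 wild-type normoxia arrays had medians of 0.805 and -0.805 from their mean, so variation between preparations was not excluded. A lower share of macrophages in the knockout cultures may account for the fall. It cannot be told apart from lower expression per macrophage, since the arrays give no count of cells and either would lower all 22 markers. A common factor would give all markers about the same fall, and their SD of 0.495, with an upper quartile of -0.859, lies between what was set for and against a lower share. This SD cannot decide, since only 4 of the 22 had a mean log2 of at least 7 and falls of weak markers can be compressed near background. For those 4 the SD was 0.177 over both sets, with 0.505 in the first and 0.179 in the second. The 4 most abundant markers, Lyz1, Lyz2, Csf1r and Ctss, fell by -1.60 to -1.19, with normoxic wild-type levels of 10.86, 10.16, 9.84 and 9.52 in the first set and 9.61, 8.90, 8.16 and 8.10 in the second, and an effect of the genotype on macrophages was not tested.

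Skeletal muscle markers were lower in the knockout in the first set alone, with a median of -2.51 over 20 genes, 1 of which is also on the myofibroblast list (camera adjusted p over both sets = 1.6e-05, and adjusted p = 0.556 with an estimated correlation). In the second set the median was 0.235 (SD 0.231), but this set cannot test loss of Hif-p4h-1 as the cause. Its wild-type arrays already had mean marker levels of 5.66 in normoxia and 5.69 in hypoxia. The first knockout arrays stood at 5.59 and 5.80 and the first wild-type arrays at 7.91 and 7.87. A loss of muscle signal could therefore hardly show in the second set, and an effect of the genotype stays open. Fewer muscle cells in the first knockout than in the first wild-type cultures may account for the lower markers and stay open too. Of the markers, 75%, 15 of 20, were lower by over 2-fold under both oxygen conditions. The median difference from the wild-type normoxia mean was 1.32 and 1.195 in the first wild-type arrays. It was -1.39 and -1.21 in the first knockout arrays and between -1.32 and -0.93 in the second set. The first wild-type arrays thus stood apart, while the first knockout arrays lay near both genotypes of the second set. The muscle markers with the highest mean over the arrays were Acta1, Mylpf, Actc1 and Tnnt2, a choice made after the result was seen. Mylpf, Actc1 and Tnnt2 stood at 10.50, 10.04 and 9.29 in wild-type normoxia of the first set and at 6.51, 6.42 and 6.65 in the knockout. Acta1, at 9.65 and 9.22, differed little. What set the first wild-type cultures apart, in dissection, embryos or culture, is not given in the sources used here and was not tested.

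The 8 arrays can be divided into 4 and 4 in 35 ways. For hypoxia against normoxia only the real division, 1 of 35, gave as many genes as its 4325 in the additive fit. The highest other was 3960, from the division by set. Among the 18 divisions with 2 arrays of each set on both sides, only the real one did, and the highest of the others gave 24. So few divisions, of arrays that deviate together, cannot exclude chance by this count alone. For knockout against wild type 3 of 35 gave as many genes as the real 84 in the additive fit, the highest other being the division by set, so by this count chance cannot be excluded. The 2 larger ones follow factors of the design, the set with 6264 and oxygen with 3987, which points to the structure of the samples. Among the 18 divisions that, like the real one, place 2 arrays of each set on both sides, the real one and that by oxygen gave as many, and the highest of the others gave 44. With the set and a mean per group in the model the genotype contrast called 35 genes, and 0 with 1 mean per genotype and set.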

How the results depend on the processing

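The alternatives with scores of macrophage or muscle markers as covariates and with 1 mean per genotype and set were added after seeing the data, and the others were planned. Counts are given in the order knockout against wild type in normoxia (5 genes), in hypoxia (4), over both (35), then hypoxia against normoxia in wild type (2237), knockout (1380) and over both (3922). Without the set they were 0, 0, 0, 20, 12 and 99, and 256 of the results named here kept their direction but lost significance while 92 held. With the set as a random block, whose correlation was 0.622, the first 5 were 0, 0, 0, 1133 and 517, and in fits of only the 2 groups compared the simple contrasts gave 0, 0, 487 and 53. Without a trend in eBayes the first 5 were 2, 0, 3, 1342 and 603. In normoxia the genotype contrast gave 11 genes with median centring (5 higher, 6 lower), 11 with a filter at the 50th percentile, which tests fewer genes, and 13 with robust settings. Over both oxygen conditions it gave 45 with median centring (17 higher, 28 lower against 8 and 27), 8 with the mean of a gene's probe sets, 20 when every probe set was tested, 84 in the additive fit and 0 with 1 mean per genotype and set, where the 19 genes named for it kept their direction but lost significance. The mean of probe sets gave 1473 for hypoxia in wild type. Asking for at least 2-fold beside the adjusted p left 3 genes for the genotype in normoxia, 17 over both, 158 and 107 for hypoxia in wild type and knockout and 135 over both. At least 2-fold in both sets without a test gave 15, 12, 13, 103, 79 and 85, and 2 for the interaction. With the macrophage score there were 32 genes for the genotype in normoxia, 3 of them among the 5, 25 in hypoxia, 2 of them among the 4, 33 over both, only 4 of them among the 35, and 2294 for hypoxia in the knockout. With the muscle score these were 38, with all 5, 19, with all 4, and 2293, and over both oxygen conditions 62, with 30 of the 35. Leaving out 1 array, where the lone array of a group is assumed to vary like the others, gave 0 to 3, 0 to 5, 3 to 58, 490 to 1975, 121 to 1335 and 2554 to 3315, and 0 for the interaction each time. The sign turned, with no call left, for Grb10 in wild-type hypoxia with the mean of probe sets (0.175) and for the medians of the macrophage marker interaction without normoxia replicate 1 of wild type (-0.085) or knockout (-0.0917) and of the myofibroblast list in hypoxia without wild-type hypoxia replicate 1 (-0.00167), in ranges up to 0.692 and 0.213. It also turned for the medians of cholesterol synthesis in wild type (-0.0892 without hypoxia replicate 1) and knockout (-0.0258 without normoxia replicate 1), of respiration in knockout (0.0075 without normoxia replicate 2) and of NRF2 target genes in knockout (0.015 with the filter at the 50th percentile), where the direction of the list test did not. Only the direction of the list test turned, again with no call, for muscle markers in hypoxia without wild-type hypoxia replicate 1 (-0.01, in a range down to -2.03) and for the macrophage interaction without knockout hypoxia replicate 2 (0.055). Quantile normalization left 343 results as they were and 5 lost significance. With an estimated correlation 3 list calls held, those of HIF target genes in the hypoxia contrasts, and 58 were lost. This form of the test also rests on only 3 residual degrees of freedom, and the 2 differences were not separated. Apart from the fewer genes or arrays where named, the cause was not tested.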

Other observations

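The Egln2 neighbour test in this part was fixed before its result was seen, and Mt1 and H2-Ab1 were chosen after their values were seen. Further gene groups moved with hypoxia over both genotypes. Glycolysis genes rose, with 15 of 18 up (median 1.11, adjusted p = 5.4e-17, and adjusted p = 0.138 with an estimated correlation). Respiration and TCA cycle genes fell, with 14 down and 2 up of 34 (median -0.08, adjusted p = 0.0132, and adjusted p = 0.693 with an estimated correlation). Myofibroblast and TGF-beta genes fell with 14 down and 1 up of 31 and matrix genes with 12 down and 2 up of 40. Interferon response genes fell with 10 down and 2 up of 34 and NRF2 target genes with 8 down and 2 up of 20. In this order the adjusted p were 0.00195, 0.00786, 0.00786 and 0.0455, and adjusted p = 0.693 each with an estimated correlation. In the knockout alone the interferon list had a median of 0, with 1 down and 2 up, and was not called (adjusted p = 0.402). The interaction, which tests the difference between the genotypes, did not keep its interferon call with an estimated correlation, so such a difference stays open. The ATF4 and unfolded protein response fell with 16 down and 5 up of 36 (median -0.20, adjusted p = 0.00604, and adjusted p = 0.273 with an estimated correlation). Cholesterol synthesis rose with 6 of 20 up (median 0.20, adjusted p = 0.0132, and adjusted p = 0.751 with an estimated correlation), but with opposite signs in the sets, at 0.47 and -0.10. Of the 8 fits without 1 array, 4 kept the cholesterol call, with a median down to 0.06, 4 the NRF2 call, down to -0.0158, and 7 the interferon call, and the other lists of this paragraph were called in all 8, with respiration down to -0.045 and myofibroblast genes to -0.13. Adjusted over the list alone, 15 glycolysis and 7 cholesterol synthesis genes rose, and 15 respiration, 16 myofibroblast, 15 matrix, 10 interferon, 8 NRF2 and 18 ATF4 list genes fell.

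Lists without a group call for hypoxia over both genotypes still held changed members. Of 43 S-phase genes 10 rose and 5 fell, and of 49 G2/M and mitosis genes 15 rose and 6 fell (adjusted p = 0.215 and 0.0836). Sox9, a regulator of cartilage formation, rose by 1.02 ± 0.084 and the keratin gene Krt19 by 1.91 ± 0.14, on lists of 14 cartilage and 14 epithelial genes with 2 and 1 up and 1 down each (adjusted p = 0.779 and 0.215). Meg3 fell by 1.34 ± 0.13 and Mirg, from the same imprinted cluster, by 1.02 ± 0.12, with 4 of 18 imprinted genes down and 4 up (adjusted p = 0.611). Of 24 Hox genes 6 rose and 1 fell, with Hoxb9 at 0.66 ± 0.083 (adjusted p = 0.18). Neural markers had 4 of 16 up and 1 down, with Stmn2 at 0.67 ± 0.091 (adjusted p = 0.322), and adipogenic genes 2 of 13 up and 2 down, with Fabp4 at 1.03 ± 0.25 (list adjusted p = 0.362), kept in 5 of the 8 fits without 1 array and down to 0.64. Of 12 endothelial markers Flt1 alone fell, and of 22 ribosomal protein genes 1 rose and 1 fell (adjusted p = 0.476 and 0.573). Macrophage markers had 1 of 22 up and 2 down and muscle markers 1 of 20 down (adjusted p = 0.309 and 0.772). Adjusted over the list alone, 12 S-phase genes rose and 6 fell, 16 G2/M and mitosis genes rose and 8 fell, 5 imprinted genes fell, and no ribosomal or muscle gene passed.

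In knockout against wild type over both oxygen conditions, smaller shifts of lists passed at the preset correlation only. Medians were -0.08 for S-phase genes, -0.09 for G2/M and mitosis genes, -0.19 for interferon response genes, -0.05 for the ATF4 and unfolded protein response, -0.10 for imprinted genes, 0.08 for myofibroblast genes and 0.06 for glycolysis. The adjusted p were 4.2e-05, 2.2e-04, 4.9e-04, 0.0229, 0.027, 1.6e-05 and 0.0402, and with an estimated correlation adjusted p = 0.618 for G2/M and mitosis genes and 0.53 for the others. In the first and second set interferon response genes stood at -0.33 and -0.03 and myofibroblast genes at 0.20 and -0.01. Both medians were thus further from 0 in the set where macrophage and muscle markers differ most. Each set has 1 array per group, and the difference between the sets was not tested. Of the 8 fits without 1 array, 3 kept the glycolysis call, 4 that of the ATF4 list and 5 those of the G2/M and imprinted lists. Without knockout hypoxia replicate 1 the G2/M median was -0.0117, and without knockout normoxia replicate 1 the imprinted median was -0.0192. Without wild-type normoxia replicate 1 the interferon median was -0.0617, and the myofibroblast median ranged from 0.0317 without wild-type hypoxia replicate 1 to 0.157 without knockout hypoxia replicate 2, both still called. Among their members, Dcn on the imprinted list was the 1 gene called over all genes, and adjusted over the list alone 4 glycolysis and 2 myofibroblast genes were higher and 1 glycolysis, 1 interferon and 2 imprinted genes lower.

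Lists too small for a test gave single values for hypoxia over both genotypes. The histone gene H3c4 rose by 0.45 ± 0.11 (adjusted p = 0.0154), and H1f2 did not pass at -0.13 ± 0.13. The erythroid genes Klf1, Hba-x and Gata1 did not pass at 0.22, -0.14 and 0.09. The Y-linked gene Eif2s3y fell by 0.38 ± 0.068 (adjusted p = 0.00497), and Kdm5d, Uty and Zfy2 did not pass at -0.26, 0.20 and 0.12. None of these genes was called in knockout against wild type. Mean log2 levels in normoxia were 9.19 in wild type and 9.46 in knockout for Eif2s3y, and 3.79 and 3.69 for Xist, a further gene of that list which the filter left untested. The metallothionein gene Mt1 rose with hypoxia by 1.58 ± 0.065 (adjusted p = 5.9e-06) and the class II major histocompatibility gene H2-Ab1 by 1.70 ± 0.12 (adjusted p = 9.5e-05).

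A chromosome segment carried along with the Egln2 mutation could change genes near Egln2. The 20 tested genes on each side had a median absolute genotype change of 0.07 over both oxygen conditions, at the 43.7th percentile of 10000 random runs of neighbouring genes, whose median was 0.0725. None of these 40 genes was called by limma, and 3 of the 35 called genes, Egln2 itself among them, lie on that chromosome. The share of all tested genes on that chromosome was not counted, so this number cannot be weighed. A median over 40 genes would not show a change in a few of them, and a carried segment may reach beyond these neighbours. The values thus show no broad change next to Egln2, and such a segment stays open as a source of the genotype calls. Single variants under a probe were not tested.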
